A study of Mus musculus with 2 samples.

How the data were processed

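DNase-seq maps open chromatin by cutting nuclei with DNase I and sequencing the cut ends. It was applied to whole spleen of 14-day-old male mice of the strain B6CASTF1/J, an F1 cross. The series held 1 group with 2 biological replicates and 1 library each. Per the labels, the material of replicate 1 came from 3 males and that of replicate 2 from 1 male, and both carry the same donor entry. No contrast between groups exists, so a difference between the libraries had no replicate check.

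Alignments were made to mm10, per the labels, and the deposited peaks, false discovery rates and footprints came as separate files for each library. The aligner, the peak caller, the footprint caller and their versions are not given in the sources used here. The deposited peak lists carry 1 signal value per peak, the authors' own, which was used to rank and describe peaks and to compare the 2 libraries. The scale of this signal is not given in the sources used here. The deposited file descriptions also list a read-depth normalized signal track, not used here. Within each library 100% of the heights were whole multiples of 1 step, within 0.05 of a step. The step was 0.00839 in replicate 1 and 0.00813 in replicate 2. If both libraries were put on the same scale, which the sources used here do not state, the depth of replicate 1 was 0.969 times that of replicate 2. The read depth itself is unknown here, so no counting interval is given for peak heights. The median peak height was 177 steps in replicate 1 and 220 steps in replicate 2.

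Each library came with 2 peak lists. The list with fewer bases was the main one and is called the strict list. The deposited false discovery rates (a p-value type of unit) list runs of bases under 0.05, and 100% of the strict peaks touched a base at or under 0.001, against 69.7% and 67.3% of the peaks in the larger lists. The footprint lists deposited by the authors hold positions, and their score column was 1 constant, so footprints could not be ranked. Every end coordinate lay within the chromosomes of the mm10 reference, and 21 chromosomes were used.

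Peaks were shared if they overlapped by at least 1 base. Overlap and position were set against 100 random placements on the same chromosome outside gaps of at least 1000 bases (permutation test, one-sided, smallest possible p = 0.0099). Promoters were the 1000 bases either side of any start site of a protein-coding gene in GENCODE M21, and a gene's promoter signal was its best peak there, or 0. The best peak was chosen in each library by itself and could lie at different sites in the 2 libraries, as at Itgb3. A correlation on the log2 scale used a pseudocount of 1. Before the data were examined, 16 gene lists, 24 consensus motifs, the tests and most alternatives were fixed. The lists cover cell types of the spleen, housekeeping genes and 4 tissues other than spleen. 1 of the listed genes was not analysed here. Each list was tested by Fisher's exact test (two-sided, Benjamini-Hochberg over the 16 lists) for a peak in both replicates against all other protein-coding genes. Genes and sites are not independent replicates, so these p-values describe the libraries. A p printed as adjusted is the Benjamini-Hochberg value. The median signal of a list was ranked among 10000 random lists of the same size. Between the replicates, the median log2 ratio of a list, less that of all genes, was ranked among 10000 random lists matched on mean signal. This was done for lists with at least 3 genes peaked in both replicates.

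Motif matches were counted in footprints inside strict peaks, widened by 5 bases, and in the rest of the peaks. The ratio of the densities was divided by the median ratio of up to 20 letter permutations of the same consensus with the same number of written CG pairs (permutation test, one-sided, smallest possible p = 0.048). CG pairs formed through letters that stand for several bases were not counted. For consensuses with such letters, the CACCC box among them, CG content was therefore not held fixed. A motif counted as past the threshold where p was under 0.05 in both libraries. The same letter permutations served both libraries, and most peaks of replicate 2 overlapped those of replicate 1. The 2 p-values of a motif are therefore not independent, and passing in both is not a replication. The named genes followed a fixed rule. It took the 2 genes of each list with the highest mean promoter signal and the first in alphabetical order without a peak, the 10 genes with the most peaks in the gene body widened by 10 kb, the 5 strongest peaks of each replicate, and the 5 genes per direction with the highest promoter signal in 1 replicate and no promoter peak in the other. Other genes named below were chosen after their values were seen.

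The steps were tested on simulated data. Of 2000 simulated sites laid out for the peak overlap, 40.0% were built to overlap and 40.0% were found to. The motif search gave the matches of an independent search for all 24 motifs, an implanted CTCF consensus was called, and 3 of 23 motifs without implants were called in that 1 simulated library. Of simulated marker lists of 16 genes among 20000, 92.5% were called when 90% of their promoters were open against 50%, and 5.0% when they were like other genes. These calls used an unadjusted p under 0.05 and 1 set of open promoters. They are therefore not the rates of the adjusted calls on both replicates, which were not simulated. Alternatives changed the peak list, the windows, the number of peaks, the scaling, the backgrounds and the replicates used. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.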

Results

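Open chromatin was mapped by DNase-seq in the spleen of 14-day-old B6CASTF1/J males, in 2 replicates of 1 group. The spleen of mice at this age holds lymphocytes, macrophages and stroma, and is a site of red cell formation. Replicate 1 had 48286 strict peaks over 9.46 Mb and replicate 2 had 28837 over 5.72 Mb, a ratio of 1.67 (mean 38561.5 ± 13752.5, SD, n = 2). The median width was 199 and 189 bases. Values below are given for each replicate, or as mean ± SD over the 2 replicates. All coordinates are on mm10.

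The first question was how far the replicates called the same sites. Both libraries had a promoter peak at 11220 of 21938 protein-coding genes (51.1%). A promoter peak in replicate 1 alone was called at 1227 genes, and in replicate 2 alone at 62. Of the peaks of replicate 2, 89.1% overlapped a peak of replicate 1, and 53.1% of the peaks of replicate 1 overlapped one of replicate 2. Random placement gave 0.789% and 0.465% (permutation test, one-sided, p = 0.0099 for both, the smallest it can give). With the same number of strongest peaks from each library the shares were 77.96% for replicate 1 and 78.22% for replicate 2. Against the larger list of the other library they were 71.05% and 90.19%. Peaks called in replicate 1 alone had a median signal of 0.907, against 3.11 for its shared peaks. In replicate 2 the values were 0.390 and 2.03. Across 50594 sites of the union, which are not independent replicates, the Pearson correlation of log2 signal was 0.873 and the Spearman correlation 0.755. At the 25148 sites called in both, the signal was higher in replicate 1 at 88.6%, with a median ratio of 1.49. Such ratios take the peak heights of both libraries to be on 1 scale, which the sources used here do not state.

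Genes with a promoter peak in 1 replicate are listed in order of signal. Hist1h3d, a histone H3 gene (signal 3.995), Cxcr5, the chemokine receptor that guides B cells to follicles (3.96), and Mzb1, a protein of marginal zone B cells and plasma cells (3.72), had one in replicate 1 alone. All 3 were in the larger list of replicate 2, with signals of 1.17, 1.18 and 1.57. Tmem198b (12.5) and Hpd (6.56) led this order, but their peaks, 971 and 991 bases from the start site, were called in replicate 2 too, at 1091 and 1031 bases and so beyond the window. In replicate 2 alone the order was Dand5 (1.57), Prph (1.29), Mroh2a (1.28), Duoxa1 (1.18) and Cd3g, a chain of the T cell receptor complex (1.04). Of these 5 genes, Mroh2a alone had no peak at its promoter in the larger list of replicate 1.

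The second question was where in the genome the peaks lay. Start sites of genes took the largest share of peaks in both libraries. In replicate 1, 46.9% of peaks lay within 1000 bases of a start site, 25.6% in introns, 22.6% between genes and 4.82% in exons. In replicate 2 the shares were 60.9%, 16.4%, 18.4% and 4.25%. Random placement put 6.95% and 7.01% at start sites (permutation test, one-sided, p = 0.0099 for both, the smallest it can give). Within replicate 1, 63.0% of the shared peaks and 28.8% of the peaks called there alone lay at start sites. With the same number of strongest peaks, the share in replicate 1 was 57.7%. Chromosome 11 was the densest, with 27.5 ± 8.99 peaks per Mb (SD, n = 2). The X, present as 1 copy in males, had 6.17 ± 1.89 per Mb, a density of 0.390 ± 0.0225 relative to the autosomes. With the same number of strongest peaks this density was 0.258 in replicate 1 and 0.406 in replicate 2. The cause of the lower density on the X was not tested.

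**Figure D1:**
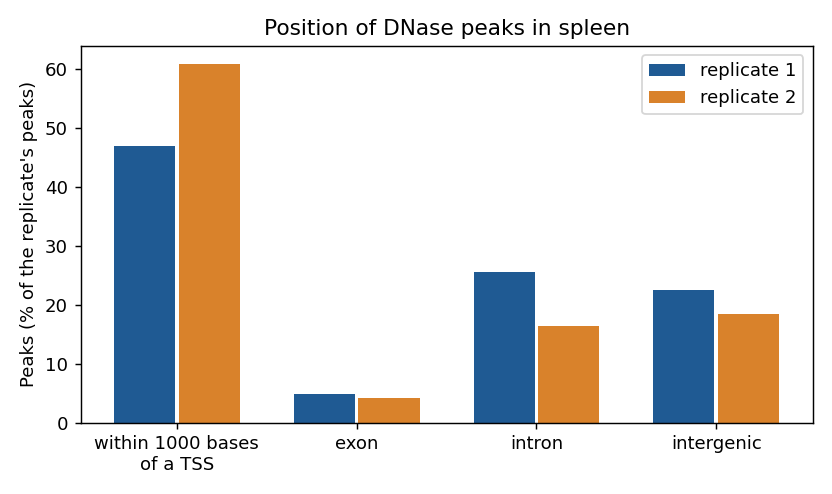
Share of the peaks of each replicate (percent, y axis) by position, in the order of priority start site, exon, intron and intergenic (x axis), with 1 bar per replicate. Start sites hold 46.9% of the peaks of replicate 1 and 60.9% of those of replicate 2.

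The strongest peaks of both replicates included chromosome 17:6430021-6430180 in Dynlt1b, a dynein light chain gene (signal 68.9 and 39.2), and chromosome 17:39846781-39846900 (49.1 and 46.9), where the annotation holds CT010467.1. Replicate 1 also had X:143482981-143483140, 35450 bases from Pak3 (43.9, against 13.2 in replicate 2), chromosome 10:81378521-81378800, 4 bases from Fzr1 (42.6), and chromosome 1:75317461-75317940 in Dnpep (40.4). Replicate 2 also had chromosome 15:99735681-99735920 in Cers5 (54.7) and a pair on chromosome 9, at 3019101-3019207 (66.7) and 3002461-3002646 (39.3). The pair was repeat sequence over 98.1% and 100% of its bases, and replicate 1 had 24.3 and 2.63 there. The peak at CT010467.1 was marked as repeat over 0% of its bases. Sequence present in several copies but not marked as repeat was not screened for, and no list of artifact regions was applied. No height here, and no peak count of a gene below, is therefore cleared of such sequence. Fgfr2, a growth factor receptor gene annotated over 2961 kb, had the most peaks by the mean of the replicates, 83 and 48. It was followed by Gse1 (43 and 30), Glis1 (4 and 49), Nfic (29 and 23), Sfi1 (25 and 26), Psd (20 and 22), Mid1 (14 and 26), Bcor (28 and 11), Iqsec1 (25 and 14) and Elmsan1 (31 and 7).

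The third question was which cell types had open promoters. At an adjusted exact p under 0.05, red cell and housekeeping genes had promoter peaks more often than other genes. Granulocyte, natural killer, stromal, liver, nerve and muscle genes had them less often. The early B cell, T cell, megakaryocyte, macrophage, dendritic and acinar lists did not pass but were also low, at 18.2% to 30%. The stromal list, which passed, stood at 22.2%. Lists were not tested against each other, so passing does not set these cell types apart from the other low lists. The background was all other protein-coding genes and was not limited to genes of single cell types. In whole spleen, peaks of a cell type with a small share of the tissue may also be missed. A low share therefore does not show that a cell type was absent or that its promoters were closed. All 12 housekeeping genes had a peak in both replicates (p = 5.04e-04, adjusted p = 0.00269, Fisher's exact test, two-sided, as for all lists), led by Rplp0, a ribosomal protein gene (signal 30.8 and 16.7), and Actb, for beta-actin (26.6 and 16.7). Of 19 erythroid genes 16 had one (84.2%, against 51.1% of other genes, p = 0.00460, adjusted p = 0.0147, exact). Tfrc, the transferrin receptor that brings iron into red cell precursors, had 15.9 ± 6.91, with a peak at chromosome 16:32608841-32609040 over its start site in replicate 1. Epor, the erythropoietin receptor, had 9.47 ± 4.54. With the strongest 50% of peaks alone the erythroid list was not past the threshold (adjusted p = 0.282, exact, with a range of 0.00373 to 0.282 over 7 alternatives). Hba-a1 and Hba-a2, near-identical alpha globin genes where reads can be shared, had no strict peak and are uncertain. Whether reads are shared between the beta globin genes Hbb-bs (6.035 and 2.749) and Hbb-bt (6.463 and 2.692) was not checked. Both count among the 16 and in the erythroid ratio between the replicates below.

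None of 14 granulocyte and monocyte genes had a peak in both replicates (p = 4.40e-05, adjusted p = 7.03e-04, exact). Cebpe, a transcription factor of granulocyte maturation, had 1.03 and S100a8 had 0.562 in replicate 1 alone, and Camp, an antimicrobial peptide gene, had none. None of 10 natural killer and cytotoxic genes did (p = 7.73e-04, adjusted p = 0.00309, exact), with Prf1, for perforin, at 0.839 and Il2rb at 0.478 in replicate 1 alone and no peak at Eomes. None of 12 hepatocyte genes did (p = 1.84e-04, adjusted p = 0.001475, exact); Apob had 0.462 in replicate 1 alone and Ahsg had no peak.

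Of 18 stromal and endothelial genes 4 had a peak in both (p = 0.0170, adjusted p = 0.0397, exact), with Col1a1, a collagen gene, at 1.87 ± 0.234, Madcam1, an adhesion molecule of spleen vessels, at 1.67 ± 0.120, and no peak at Ccl19. Of 12 neuron genes 2 did, Syn1 (1.58 ± 0.619) and Rbfox3 (0.919 ± 0.161), with none at Gad1, and of 12 skeletal muscle genes 2 did, with none at Acta1 (p = 0.0198 and adjusted p = 0.0397 for each, exact). The muscle genes were Ckm (2.88 ± 0.123) and Mylpf (7.54 ± 4.09), and the peak at Mylpf also lay within 1000 bases of a start site of Tbc1d10b. In replicate 1 taken alone the natural killer, stromal, neuron and muscle lists were not past the threshold (adjusted p = 0.0652, 0.113, 0.773 and 0.0873, exact). The genes of these 4 lists with a peak there were 2 of 10, 6 of 18, 6 of 12 and 3 of 12. Over 7 alternatives their adjusted exact p ranged from 0.00292 to 0.0652, 3.68e-04 to 0.113, 0.00513 to 0.885 and 0.00902 to 0.119.

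The other lists were not past the threshold. Of 16 B cell genes 11 had a peak in both replicates (p = 0.212, adjusted p = 0.231, exact), led by Pax5, the factor that sets B cell identity (6.01 ± 2.94, chromosome 4:44704441-44704740 in replicate 1, 435 bases from a start site), and Cr2, a complement receptor (5.17 ± 2.17). In replicate 1 alone 15 of the 16 had one (adjusted p = 0.00744, exact, with a range of 0.00722 to 1 over 7 alternatives), all but Btk. Of 16 T cell genes 4 did (p = 0.0447, adjusted p = 0.0716, exact), led by Lck, a kinase of T cell receptor signalling (5.92 ± 0.447), and Cd3d (2.00 ± 1.07), with none at Cd247. The T cell list was past the threshold, and lower, with a 500-base window (18.8%, adjusted p = 0.0252, exact) and with the strongest 50% of peaks (6.25%, adjusted p = 0.00513, exact), with a range of 0.00513 to 1 over 7 alternatives. The counts were 2 of 8 early B cell genes (Blnk 3.60 ± 2.27, Vpreb1 3.46 ± 1.12, with a peak also within 1000 bases of a start site of Top3b, and none at Dntt), 3 of 12 megakaryocyte genes (Itga2b 8.64 ± 2.02, Itgb3 3.04 ± 1.59, none at Gp1ba) and 4 of 15 macrophage genes (Slc40a1, the iron exporter, 3.45 ± 0.825, Spi1 3.01 ± 1.35, none at Adgre1). They were 3 of 10 dendritic cell genes (Zbtb46 5.28 ± 0.953, Irf8 4.91 ± 2.01, none at Batf3), 5 of 8 stem and progenitor genes (Meis1 2.30 ± 1.23, Mycn 1.87 ± 0.509, none at Cd34) and 2 of 11 pancreatic acinar genes (Cela1 2.99 ± 1.05, Rbpjl 1.83 ± 0.397, none at Amy2a5), with an adjusted exact p between 0.0617 and 0.727 for these 6 lists. Of these, the acinar list was past the threshold, and lower, with the larger peak lists (adjusted p = 0.0374, exact, range 0.0374 to 0.118 over 7 alternatives), and the stem and progenitor list with the strongest 50% of peaks (adjusted p = 0.0245, exact, range 0.0245 to 1). Taken alone, replicate 1 had a peak at 7 of 16 T cell, 4 of 8 early B cell, 4 of 12 megakaryocyte and 7 of 15 macrophage genes. It had one at 5 of 10 dendritic cell, 6 of 8 stem and progenitor and 3 of 11 pancreatic acinar genes. By median promoter signal, the housekeeping list stood above the central 95% of random lists (percentile 99.85), with the erythroid list at 84.6 and the B cell list at 73.6. No list could fall below that range, since random lists often had a median of 0 too.

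**Figure D2:**
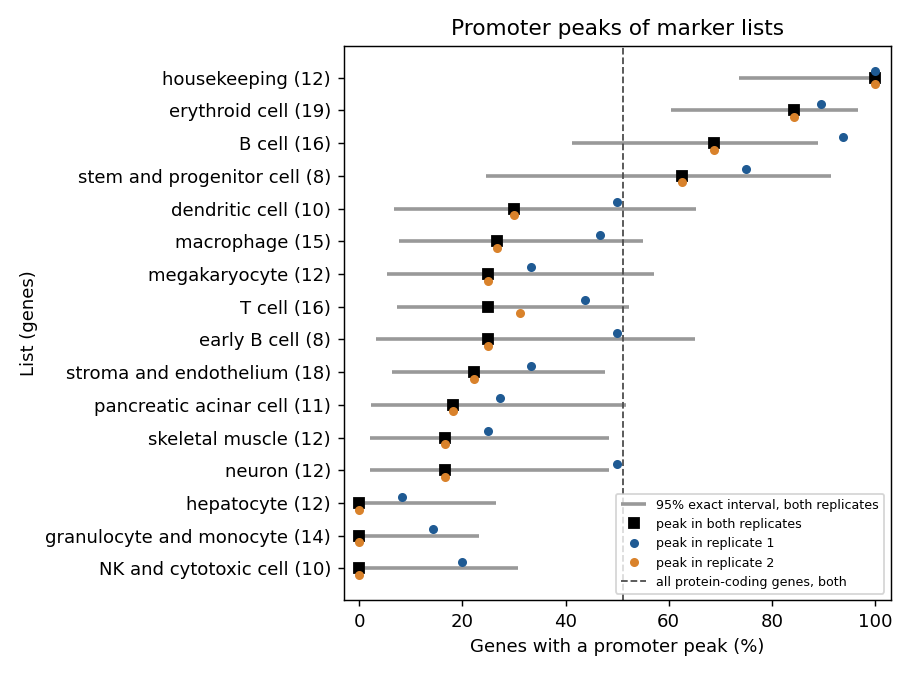
Percent of the genes of each list with a promoter peak (x axis) for the 16 lists (y axis, genes in parentheses), in both replicates (squares with 95% exact intervals) and in each replicate (circles), with all protein-coding genes as a dashed line at 51.1%. Housekeeping and erythroid genes lie above the line with their intervals.

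The fourth question was whether the promoters of any cell type differed between the libraries by more than other promoters. Genes of B cells and red cells had relatively more signal in replicate 1. Over the 11220 genes with a peak in both, the median log2 ratio of replicate 1 over replicate 2 was 0.70, and the values that follow are relative to it. The B cell list stood at 0.49, with 10 of 11 genes above 0, and the erythroid list at 0.37, with 14 of 16 above 0, both at the 100th percentile of matched random lists. At Cd22 and Spib of the B cell list, and Ermap and Trim10 of the erythroid list, the ratio compares peaks at different sites. Of the other 7 lists measured none was outside the central 95%. T cell genes were at 0.24 (percentile 96.6), housekeeping at 0.11 (71.2), dendritic at 0.16 (87.3) and stem and progenitor at -0.14 (68.6). Macrophage genes were at -0.20 (39.6), megakaryocyte at -0.22 (19.6) and stromal and endothelial at -0.61 (4.33). With 1 library each these percentiles describe the 2 libraries, and the labels give 3 males for one and 1 male for the other.

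**Figure D3:**
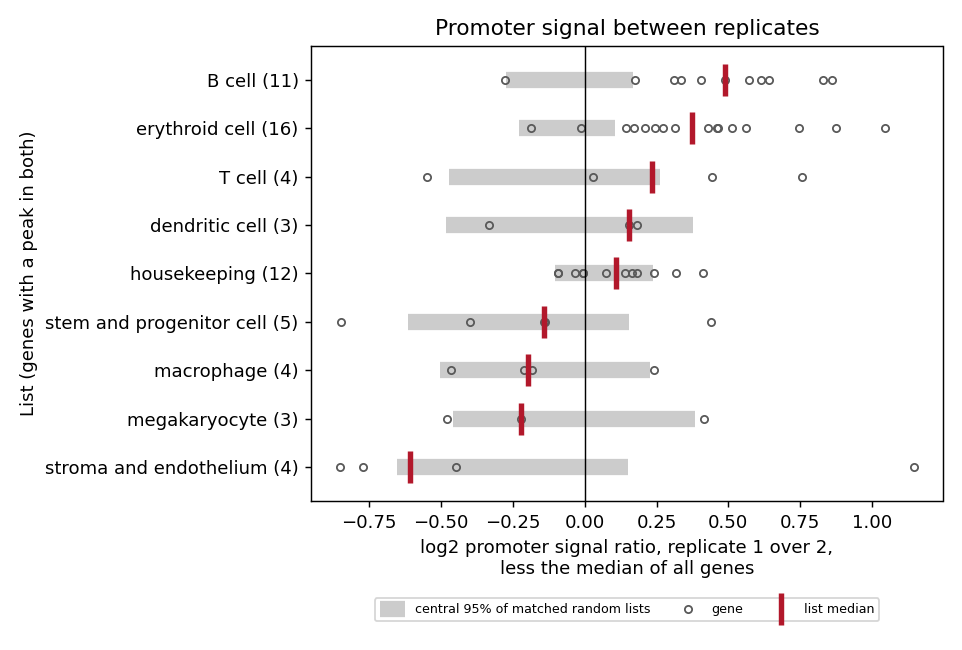
Log2 ratio of promoter signal, replicate 1 over replicate 2, less the median of all genes (x axis), for the genes of each list with a peak in both replicates (open circles) and the list median (red bars), over the central 95% of matched random lists (grey). The medians of B cell (0.49) and erythroid genes (0.37) lie outside the grey range.

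The last question was which sequence motifs lay in footprints, short stretches protected from cutting inside open sites. Footprints held CTCF, NRF1, CRE, ETS, NFY and CACCC box motifs more densely than the rest of the peaks. The log2 enrichment over letter permutations was 6.66 ± 1.78 for CTCF, which organises chromatin loops, 5.66 ± 0.24 for NRF1 and 3.68 ± 0.04 for CRE (SD, n = 2). It was 1.93 ± 0.02 for ETS, 1.104 ± 0.17 for NFY and 0.93 ± 0.08 for the CACCC box of KLF1-type factors (SD, n = 2). The consensus of the CACCC box (CCMCRCCC) also matches every GC box (GGGCGGGG, read on the other strand). Footprints of replicate 1 held 7224 GC box and 12598 CACCC box matches, and those of replicate 2 held 6054 and 9592. So the CACCC box enrichment cannot be told apart from that of the GC box. For REST, a repressor of neuronal genes, 31 matches lay in footprints and 1 in the rest of the peaks of replicate 1, and 15 and 0 in replicate 2. REST also met the threshold, but the highest ratio among its letter permutations was that of 0 matches, so its p compares with counts of 0 and carries little information. For footprints over 1000 bases from a start site, CTCF and NRF1 were past the threshold, as was REST with the same limit, and ETS (1.305, permutation p = 0.238), CRE (2.39, permutation p = 0.0952), NFY (0.54, permutation p = 0.0952) and the CACCC box (0.24, permutation p = 0.190) were not. With unwidened footprints NFY was not past it either (permutation p = 0.0952). Each of the 7 motifs, REST included, had a permutation p = 0.048 (one-sided) in both libraries, the smallest possible. After Benjamini-Hochberg adjustment over the 24 motifs no motif was under 0.05 in either library (smallest adjusted permutation p 0.104 and 0.143), and with 20 permutations an adjusted value under 0.05 would need nearly every motif at the smallest p.

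The other motifs were not past the threshold in both libraries. EBF, for a B cell factor, had 1.94 in replicate 1 (permutation p = 0.048) and 0.35 in replicate 2 (permutation p = 0.238). The TAL1-GATA composite of red cell factors had 1.18 (permutation p = 0.048) and 0.64 (permutation p = 0.143). IRF (0.74) and HNF4 (0.64) were past the threshold in replicate 1 alone, and MEF2 (0.86) in replicate 2 alone. Differences in motif enrichment between the libraries were not tested. PU.1 (-0.08 ± 0.25), RUNX (0.24 ± 0.29) and GATA (0.34 ± 0.26) were not past it in either library. With a background of 50 to 150 bases from the footprint, RUNX (0.73), GATA (1.01), TAL1-GATA (1.54) and MEF2 (1.81) were past the threshold in both libraries (permutation p = 0.048), and PU.1 and EBF were not. The GC box of SP and KLF factors (0.93 ± 0.15) had 6 permutations, so its p could not go below 0.143. YY1 stood at 1.28 ± 0.06, OCT at 0.58 ± 0.01, TCF/LEF at 0.30 ± 0.12, AP-1 at 0.27 ± 0.33, NF-kB at 0.11 ± 0.26, the E-box CAGGTG at 0.22 ± 0.03 and CAGCTG at -0.12 ± 0.10, all short of the threshold in both. HNF1 had 0 matches.

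The 191945 footprints of replicate 1 and 125693 of replicate 2 (mean 158819 ± 46847.2) had a median width of 10 and 11 bases. Within strict peaks, 50.4% and 74.2% overlapped a footprint of the other replicate, against 36.5% and 53.3% for random places in the same peaks (permutation test, one-sided, p = 0.0099 for both). Footprints lay at start sites in 53.0% and 63.2%.

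**Figure D4:**
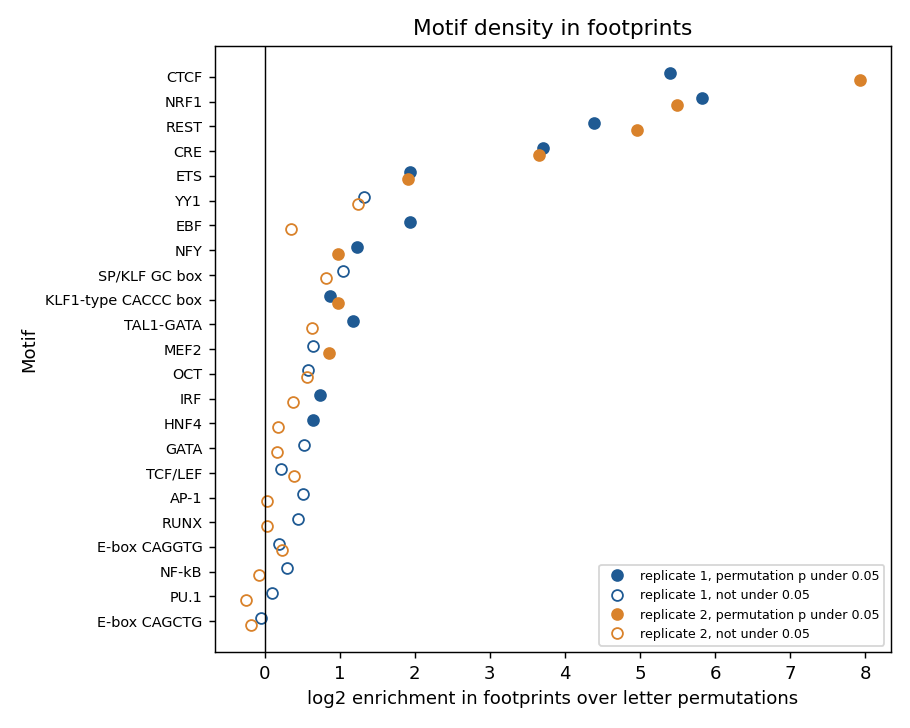
Log2 enrichment of motif matches in footprints over letter permutations of the same consensus (x axis) for the motifs with matches (y axis), with 1 circle per replicate, filled where the permutation p was under 0.05. CTCF stands at 5.40 in replicate 1 and 7.92 in replicate 2, and NRF1 at 5.82 and 5.49.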

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

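Leaving out bins of clustered peaks and taking the other library's larger list were chosen after seeing the data, and the other alternatives were fixed before. Of 58 alternative values of the main results 48 kept their direction and side of the threshold, moved less than their spread or, for counts, stayed within a fixed factor of the main count. A count of lists or motifs can stay so while its members change. Part of the 48 could hardly have changed. With 1 replicate left out, the X density always lies within the SD of the 2 replicates. Overlap and start-site shares lay far above random placement to begin with. A promoter peak was called in both libraries at 11220 genes and in replicate 2 at 11282, so leaving out replicate 1 changed the promoter calls little by construction. The number of lists past the threshold, 8, was 5 with a 2000-base window, and 5 to 8 with 1 replicate left out, the lower with replicate 1 alone. The 500-base window kept every call and gained the T cell list. With the larger lists the B cell and acinar lists were gained, and the natural killer, stromal, neuron and muscle lists lost. With the strongest 50% of peaks the T cell and stem and progenitor lists were gained, and the erythroid and muscle lists lost. The number of motifs, 7 with REST, was 11 with a background of 50 to 150 bases from the footprint and 3 for footprints over 1000 bases from a start site, and 8 to 11 with 1 replicate left out. The correlation, 0.873, was 0.950 for untransformed signal and 0.953 for sites called in both. The X density relative to autosomes, 0.390, was 0.418 with the larger lists and 0.332 ± 0.104 (SD, n = 2) with the same number of strongest peaks. The strongest 50% of peaks number 19281 by construction. The cause of the other changes was not tested. Peaks at start sites stayed above random placement in every alternative run (45.8% to 60.9%). Of 405 values of single lists and motifs, 342 kept their call, 18 lost it, 14 gained it, 20 without a test moved and 11 reversed. The reversed ones were T cell promoters at 56.2% with the larger lists, stem and progenitor promoters at 50% with a 500-base window and 0% with the strongest 50% of peaks, NF-kB at -0.36 with unwidened footprints, OCT at -0.18 and the E-box CAGCTG at 0.055 with unwidened footprints, CAGCTG at 0.059 and PU.1 at 0.80 with the nearby background, and PU.1 at 0.062 with footprints widened by 10 bases. With 1 replicate left out, PU.1 ranged from -0.250 to 0.0966 and NF-kB from -0.0702 to 0.294, each crossing 0. The strongest 50 percent of footprints and the same number of strongest footprints were not run, since footprints carry no ranking score. No paired analysis was possible because there was 1 group. Read depth is unknown here, so weak peaks of replicate 1 missing from replicate 2 cannot be called absent.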

Other observations

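The tests of sequencing depth, of 1 ratio at all sites and of distal sites without CTCF were chosen only after the related results were seen, and the distal comparison was added because its first form proved unspecific. The rule that a motif test decides nothing where NFY, AP-1 or MEF2, taken as controls, pass too was also added after those values were seen. It was applied to both comparisons.

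At distal sites, away from start sites, the ratio of signal between the libraries differed by motif. Over 9430 distal sites called in both libraries the median log2 ratio of replicate 1 over replicate 2 was 0.37, against 0.65 at start sites. Sites with neither the E-box CAGGTG nor CTCF stood at 0.46 (5915 sites). Sites with a TAL1-GATA composite stood at 1.20 (121 sites), GATA at 1.08 (496), OCT at 1.03 (86), PU.1 at 0.92 (301), MEF2 at 0.89 (27), ETS at 0.88 (21), EBF at 0.87 (92), CRE at 0.78 (61), RUNX at 0.77 (276), NFY at 0.76 (427), the CACCC box at 0.74 (1505), AP-1 at 0.73 (367), the E-box CAGCTG at 0.72 (1453), NF-kB at 0.68 (247), the GC box at 0.65 (526), IRF at 0.63 (139), NRF1 at 0.62 (34), TCF/LEF at 0.58 (211) and the E-box CAGGTG at 0.47 (1571). CTCF sites without a TAL1-GATA motif stood at 0.15 (1936). These medians are not adjusted for GC content or signal, so their order is in part that of GC content and signal. After the adjustment described below, 15 of 19 motifs remained higher than other distal sites without CTCF, the GC box by 0.083. Among those that did not were CRE (-0.0029) and NRF1 (-0.047). On chromosome 12, the immunoglobulin heavy chain locus showed opposite patterns in neighbouring bins of 100 kb. The bin from 113400001 to 113500000, with Ighm, Ighd and the joining segments, held 33 peaks in replicate 1 and 1 in replicate 2. The bin from 113300001 to 113400000, with Ighg1, Ighg3 and Ighg2b, held 2 and 29. The peaks of both bins were weak (median signal 0.353 in replicate 1 and 0.211 in replicate 2, against 1.49 and 1.82 for the other peaks). Both bins were picked by the rule for clusters described below. The bin with Ighm is 1 of 3 with the excess in replicate 1, and the bin with Ighg1 is 1 of 14 with the excess in replicate 2. No explanation was found for the clusters of replicate 2, and none was tested for those of replicate 1. No test of the contrast between the 2 bins was run.

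Replicate 1 had more peaks than replicate 2. Deeper sequencing of replicate 1 is argued against by the depth ratio of 0.969 from the steps of peak heights, provided that both libraries were put on the same scale. Lower signal at all sites alike in replicate 2 is argued against as the whole cause, since the ratio between the libraries was not 1 value: distal sites of each of 10 motifs exceeded CTCF sites of the same signal, by at least 0.50 on the log2 scale. The test set beforehand decided nothing by itself, since once divided by the median ratio of shared peaks, 64.5% of the peaks called in replicate 1 alone fell below the 10th percentile of replicate 2 heights, between its bounds of 80% and 50%. Lower signal that differs between classes of sites, and a difference between material of 3 males and of 1 male, were not tested and may contribute.

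B cell and erythroid promoters were relatively stronger in replicate 1. GC content is argued against as the whole cause, since after removing linear trends on GC content and on signal the lower of the 2 percentiles was 99.99; that adjustment also put T cell (97.78) and stromal genes (2.12) outside the central 95%. A larger share of B cells or of erythroid cells in replicate 1 may account for it, and distal EBF and TAL1-GATA sites, as set beforehand, exceeded CTCF sites of the same signal by 0.65 and 0.90 on the log2 scale, but so did all 10 motifs set against CTCF, NFY, AP-1 and MEF2 included. Against distal sites without CTCF, adjusted for GC content and signal, 15 of 19 motifs were higher (adjusted permutation p under the threshold), among them TAL1-GATA by 0.60, GATA by 0.59, PU.1 by 0.50, EBF by 0.42, MEF2 by 0.40, AP-1 by 0.28 and NFY by 0.22, while ETS (0.29), the E-box CAGGTG (0.015), CRE (-0.0029) and NRF1 (-0.047) were not. Motifs taken as controls passed as well, NFY and AP-1 by smaller amounts. Sites with these motifs could also carry EBF, GATA or PU.1 motifs. Whether the controls are unrelated to cell type was not tested. Cell shares therefore cannot be told apart from a shift common to several, though not all, classes of distal motif sites.

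In 14 bins of 100 kb, replicate 2 held at least 20 peaks and at least 4 times as many as replicate 1, 456 peaks in all with a median signal of 0.228, against 1.82 for its other peaks. They include Glis1 (0 and 47 peaks), the Hoxa genes (4 and 25) and a bin at Mid1 (2 and 20), where the peaks were not weak (median 2.32). The same rule found 3 bins with the excess in replicate 1, with 81 of its peaks. These were at Elmsan1 (27 and 6), Bcor (21 and 1) and Ighm (33 and 1), and no explanation was tested for them. For the clusters of replicate 2, reads of repeated sequence are argued against as the whole cause, with 12.9% of the peaks mostly soft-masked. That share was above the 2.99% of all peaks of replicate 2, so repeats may contribute. Repeated sequence outside soft-masked bases was not tested. Sites just under the calling threshold in replicate 1 are argued against, with 9.21% of the cluster peaks in its larger list. High GC content is argued against too, with a median of 53.0% against 60.6% for the other peaks. What made these clusters stays open, and no biological explanation was tested.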
